A study of Mus musculus with 5 samples.

How the data were processed

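Cells of the mouse ocular area were profiled by droplet single-cell RNA sequencing. Per the labels, 1 wild-type C57BL/6J embryo was taken at each of 5 stages, with 12, 16, 20, 24 and 26 somites, and both optic areas were dissected by needle. The tissue was dissociated with trypsin and about 2000 cells per sample were prepared with the third version of the 10x Genomics Chromium 3′ kit, per the labels' protocols. Each stage therefore had 1 sample and no replicate.

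The deposited matrix holds UMI counts, whole numbers of distinct RNA molecules per gene and cell, which the authors did not normalise as far as the values show. Cell Ranger and the mouse build mm10, also called GRCm38, are named in the submitters' processing notes. The version of Cell Ranger, its rule for calling cells and any equalising of depth between libraries are not given in the sources used here. A single matrix pools all samples, with 27998 genes and 8194 barcodes. Each barcode has 16 bases and a suffix from 1 to 5. The suffix separates the 5 libraries but names no stage, so the libraries were left unassigned and are numbered by their suffix. Whether the numbers follow the order of the stages is not given. The comparison between stages was not made. Values per library are given one by one, without a test.

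The filters on barcodes, the settings of the first clustering, the marker and readout lists, the size rule and the thinning depths were fixed before the data were examined. Barcodes with at least 1000 genes and at most 10% mitochondrial UMIs were kept, which left out 22 barcodes over the mitochondrial limit and 0 under the gene minimum. Doublets were called in each library with Scrublet, in scanpy 1.11.5, at an expected rate of 6%, and 68 barcodes (0.832%) were removed. The caller marked 1.39% and 1.76% of the barcodes in libraries 1 and 2 but 0.451%, 0.268% and 0.459% in libraries 3, 4 and 5, each below the expected rate. The remaining 8104 cells were scaled to 10000 UMIs, log-transformed, reduced to 2000 highly variable genes and 30 principal components, joined to 15 neighbours, and clustered with the Leiden method at resolution 1, with no integration of libraries. Ribosomal, mitochondrial, haemoglobin and sex-linked genes and all readout lists were left out of the clustering, and 0 readout genes were in the variable set. After the data were seen, the neuroepithelial and the ectodermal clusters were each clustered again. This gave 25 main clusters, 15 neuroepithelial sub-clusters and 12 ectodermal sub-clusters.

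Clusters were named only from marker lists for optic vesicle, telencephalon, diencephalon and hypothalamus, midbrain and hindbrain, surface ectoderm, lens placode, other placode, cranial neural crest mesenchyme, migratory neural crest, head mesoderm, endothelium, erythroid, myeloid, megakaryocyte, neuron, endoderm and extraembryonic endoderm. Lists for neural retina, retinal pigment epithelium, optic stalk and dorsal optic vesicle served for regions. The markers were fixed beforehand, but how they were scored was set after the data were seen. A name needed at least 3 markers with at least 10 UMIs and a 2-fold higher CPM, after adding 5 CPM to both sides. It also needed no contradiction among the 10 leading genes. Main clusters and ectodermal sub-clusters were set against all other cells. Neuroepithelial sub-clusters were set only against crest, head mesoderm, endothelium, erythroid and surface ectoderm cells. Their markers thus do not show a rise over other neuroepithelium, and Rax and Lhx2 also passed in the other forebrain sub-clusters. Also after the data were seen, a neuroepithelial sub-cluster was called optic vesicle-like only with at least 5 of the 10 optic vesicle markers, and telencephalon-like and diencephalon-like sub-clusters were joined as other forebrain. Likewise, 3 kinds of cluster were kept out of every class. These were a cluster led by Nkx2-1 and Shh, and clusters with little of the nuclear RNA Malat1, here called nucleus-depleted. The remaining kind had markers of both neuroepithelium and neural crest and is here called mixed. The name nucleus-depleted stands for little Malat1 only, and whether a nucleus was missing was not settled.

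The readouts were 315 genes in 16 lists, of which 313 genes were in the matrix. The lists were the FGF, BMP and TGF-beta, WNT, Hedgehog, retinoic acid and Notch pathways, Eph, ephrin and guidance, adhesion and basement membrane, S phase, G2 and M phase, glycolysis, heterochronic RNA-binding and MYC genes, neurogenesis onset, imprinted genes, sex-linked genes and dissociation stress. Raw UMIs were summed over the cells of a class and divided by the class total to give CPM, the unit computed here from the deposited counts. Classes were compared by the ratio of their CPM with an exact 95% interval for the ratio of Poisson counts. Shares of cells carry exact Clopper-Pearson 95% intervals. All intervals cover counting error only, not differences between embryos, and cells were not treated as replicates. A readout gene met the size rule if its CPM ratio was at least 2 in either direction, the interval excluded 1.5, the higher class had at least 50 UMIs and 20 CPM, and the direction was the same in every library with at least 30 cells of both classes. A class needed 50 cells to be compared.

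The text names up to 15 genes with the largest ratio in each direction, the 2 members of each list with the most UMIs, and a fixed set of eye-field and signalling genes whatever their value. Within the optic vesicle-like class, readout and marker genes were called different between libraries if the highest library had at least 50 UMIs and at least 4 times the CPM of the lowest, and the 20 with the largest ratio are named. A count of 0, and between libraries any count below 3, was set to a floor of 3 counts for a ratio. A share of 0 is given with the largest share that 3 counts allow in place of its interval. For cell cycle scores, each cell was thinned at random to 5000 UMIs, and the unthinned values are also given. Alternatives changed the doublet and gene filters, the clustering resolution, the genes allowed into the clustering, the scaling, the weight of libraries, the size rule, the thinning depth, and the libraries included, each left out in turn. Further alternatives chosen after seeing the data moved the unnamed clusters into classes, left out clusters of low UMI content in library 5, and summed only libraries with at least 30 cells of both classes. Some genes that these rules name, and 1 planned comparison within the optic vesicle-like class, are not reported here, but such genes remain in the counts.

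The ratio step was tested on simulated counts for 27998 genes with 200 changed, once for each of the 4 comparisons made. The counts were Poisson draws from a profile shared by both classes and all libraries. Changed genes were drawn from those at 20 CPM or more. All genes simulated at 3-fold or 6-fold were recovered in each comparison, those at 1.5-fold were not called, and 0 unchanged genes were called. Since the rule needs a ratio of at least 2, the outcomes for 1.5-fold and unchanged genes were largely fixed in advance. The intervals held the true ratio for 95.9% of genes against surface ectoderm, 95.2% against mesenchyme, 95.1% against other forebrain and 95.7% between the regions of the optic vesicle. The simulation held no differences between libraries or embryos, so it checks counting error only. Coordinates are from GENCODE mouse release 21 on GRCm38, which holds the identifiers of 27645 matrix genes. Computation used Python 3.11.15, anndata 0.12.19, igraph 0.11.9, scikit-learn 1.9.0, scipy 1.17.1, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.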

Results

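The study followed the early murine eye field across 5 somite stages, with 1 embryo per stage, and the labels ask how progenitors of the retina differ between stages. The matrix held 257637891 UMIs in 8194 barcodes. Libraries 1 to 5 had 1307, 1656, 1996, 1490 and 1745 barcodes in turn. Their totals were 41694822, 47890169, 72925591, 51678161 and 43449148 UMIs. The median barcode had 30922, 26784, 30752, 28563 and 20713 UMIs in libraries 1 to 5, and from 4420 genes in library 5 to 5098 in library 1. Because the library numbers name no stage, the cell classes within the ocular area were compared, and the optic vesicle-like class was described library by library. Each stage had 1 embryo, and libraries of different stages were not treated as replicates, so no p-value is given and every interval covers counting error only.

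Neuroepithelium of the eye field made up the largest class over the pooled cells, though not in libraries 1 and 4. Of the 8104 cells kept, 2172 were optic vesicle-like (26.8%, 95% interval 25.8 to 27.8%), and a further 1181 (14.6%, 13.8 to 15.4%) were other forebrain-like. Around the vesicle, 1720 cells were cranial neural crest mesenchyme-like (21.2%, 20.3 to 22.1%), 433 head mesoderm-like (5.34%), 388 surface ectoderm-like (4.79%, 4.33 to 5.28%) and 388 endothelium-like (4.79%). Erythroid-like cells were 3.12% of the total, migratory neural crest-like cells 1.10%, neuron-like cells 0.42%, myeloid-like cells 0.308% and megakaryocyte-like cells 0.148%. All 11 endoderm-like cells (0.136%) came from library 1. No cluster met the criteria for midbrain and hindbrain, other placode or extraembryonic endoderm. Another 3 kinds of cluster stayed unnamed, with 9.74% of cells nucleus-depleted, 3.33% mixed and 4.18% in the ventral cluster led by Nkx2-1 and Shh.

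Libraries differed in these shares, which the extent of each dissection can set. The optic vesicle-like class took 15.8%, 22.1%, 26.3%, 18.8% and 46.8% of cells in libraries 1 to 5. Crest mesenchyme-like cells were 19.5% of library 1 and 23.8% of library 4, above the vesicle in both. Other forebrain-like cells were 25.1% of library 1 and 16.0%, 16.1% and 18.9% of libraries 2, 3 and 4. Library 5 had 0 such cells, which allows a share of up to 0.173%. Head mesoderm-like cells ranged from 0.288% in library 5 to 11.9% in library 1, and crest mesenchyme-like cells from 15.1% in library 3 to 30.1% in library 5. The unnamed ventral cluster held 0.235%, 7.80%, 6.90%, 4.78% and 0.115% of libraries 1 to 5. Nucleus-depleted clusters held 15.6%, 11.6%, 7.05%, 9.76% and 6.80%. Mixed clusters held 0.062% of library 2 and 5.89%, 7.07% and 2.71% of libraries 3, 4 and 5, and 0 cells of library 1, which allows up to 0.235%. Retina-like and pigment-epithelium-like sub-clusters came almost entirely from library 5, with 299 of 300 and 147 of 150 cells, so each may describe that library as much as a region. An ectodermal sub-cluster of 24 cells, all from library 5, had 1 lens placode marker (Pitx3) against 3 surface ectoderm markers among its 10 leading genes, and it was left in the surface ectoderm-like class, where the lens gene Foxe3 had 0 UMIs.

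**Figure D1:**
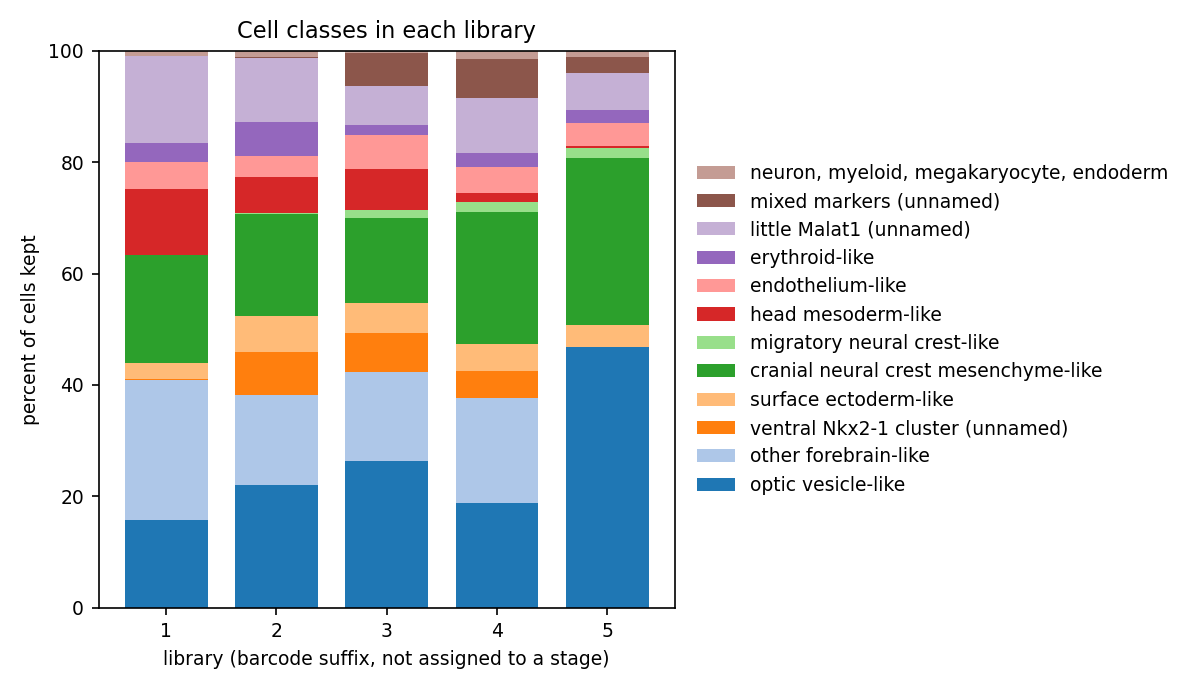
Share of cells (percent, vertical axis) of each class in each of the 5 libraries, as stacked bars that start at 0. The optic vesicle-like share runs from 15.8% in library 1 to 46.8% in library 5, and library numbers are not assigned to stages.

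Against surface ectoderm-like cells, the optic vesicle-like class had more Fst and Fgf15 RNA, and less Wnt6, Cdh1 and Cdh3 RNA. Fst (ENSMUSG00000021765, chromosome 13, 114452290 to 114458951), an activin antagonist, was at 54.2 CPM against 0.91 CPM, a ratio of 59.5 (33.2 to 119). Fgf15 (ENSMUSG00000031073, chromosome 7, 144896531 to 144900953) was 26.3-fold higher (18 to 39.9), at 58.7 CPM. Wnt6 (ENSMUSG00000033227, chromosome 1, 74771892 to 74785322) was at 84.8 CPM in surface ectoderm-like cells and 0.088 CPM in the vesicle, 962-fold lower (465 to 2399). The epithelial cadherins Cdh1 and Cdh3 were 197-fold (132 to 310) and 90.7-fold (63.0 to 135) lower in the vesicle. Of 313 readout genes, 12 were higher, 30 lower and 271 met neither side of the size rule, from 2172 against 388 cells in 5 libraries. With readout lists allowed in the clustering, Fgf15 was 17.3-fold higher (12.8 to 23.9) and Cdh1 at 0.0019 of the ectoderm level, and without library 3 Cdh1 was at 0.0033 of it.

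In the FGF list of 21 measured genes, 1 was higher and 4 were lower, with Fgf17 12.0-fold lower (9.95 to 14.6), the FGF target Etv5 8.55-fold lower (7.31 to 10.0), the target Dusp6 5.25-fold lower (4.64 to 5.94) and Fgfr2 also lower. Fgf17 in the vesicle rested on library 1, at 26.0 against 52.7 CPM there, and its ratio was 0.209 with libraries weighted equally, 0.0085 without library 1 and 0.0011 with readout lists allowed in the clustering. The ratio of Dusp6 was 0.338 with the ventral cluster counted as optic vesicle. The WNT list of 35 split into 4 higher and 3 lower. Dkk1 (9.16-fold, 6.43 to 13.5) and Sfrp1 (4.64-fold, 4.23 to 5.11), both WNT antagonists, were higher with Wnt7b (6.37-fold, 4.75 to 8.77) and Nkd1 (3.71-fold, 2.90 to 4.81), while Wnt4 was 54.7-fold lower (38.8 to 79.2) and Wls also lower. Wnt7b was 12.1-fold higher without library 1 and 3.93-fold higher without library 5. In the BMP and TGF-beta list of 27, Fst was higher, and Msx1 (5.50-fold, 4.79 to 6.31), Bambi and Id1 were lower. In the retinoic acid list of 15, 0 were higher and Rarg, Aldh1a3 and Crabp1 were lower. Rarg was 14.6-fold lower (11.7 to 18.3). Aldh1a3 (ENSMUSG00000015134, chromosome 7, 66390890 to 66427517), which makes retinoic acid, was at 122 CPM against 1010 CPM, 8.29-fold lower (8.07 to 8.52), and at 0.0409 of the ectoderm level without library 5. In the Notch list of 18, the effector Hes5 (3.68-fold, 2.93 to 4.69) and Dtx4 (2.31-fold, 1.90 to 2.83) were higher and 0 were lower.

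The adhesion and basement membrane list of 24 gave 2 higher and 7 lower genes. Cdh11 was 14.8-fold higher (10.1 to 22.7) and Vim, an intermediate filament gene, 6.63-fold higher (5.78 to 7.65), while Lama5 was 6.74-fold lower (5.74 to 7.91), Col4a2 4.42-fold lower (3.99 to 4.90), and Col4a1, Fn1 and Lamc1 were also lower. Among 28 guidance genes Efnb3 was higher (3.16-fold, 2.63 to 3.83) and Sema3a lower (13.9-fold, 12.1 to 16.0). Of 18 glycolysis genes, only the glucose transporter Slc2a3 met the rule, at 45.9 against 462 CPM (10.1-fold lower, 9.66 to 10.5). Imprinted genes gave 1 higher and 5 lower of 14, with Plagl1 6.15-fold higher (4.98 to 7.68), the growth factor Igf2 5.58-fold lower (5.27 to 5.90, and 0.0576 of the ectoderm level without library 5), and H19, Peg3, Cdkn1c and Igf2r lower. Gas1 was the only 1 of 12 Hedgehog genes past the rule (2.62-fold lower, 2.48 to 2.76), Dnmt3b the only 1 of 16 heterochronic genes (lower), and Ier2 the only 1 of 12 stress genes (2.13-fold lower, 2.01 to 2.26). None of the 26 S phase, 30 G2 and M phase, 12 neurogenesis or 5 sex-linked genes met the rule. Bmp4 was at 19.2 against 46.2 CPM, but lower in only 4 of 5 libraries, and Bmp7 had a ratio of 1.44 toward the ectoderm. Sfrp2 had a ratio of 2.04 (1.92 to 2.17) with 4 of 5 libraries in its direction. The optic vesicle markers Rax (35.2-fold, and 59.7-fold without library 5) and Lhx2 (29.5-fold) describe how the class was named. Six3 had a ratio of 1.25 (1.19 to 1.31), higher in 4 libraries and lower in 1. Six6 had a ratio of 1.15 (1.10 to 1.2) but went both ways, higher in 2 libraries and lower in 3, with 134 against 232 CPM in library 1 and 326 against 68.8 CPM in library 5. Pax6 was at 235 against 115 CPM, Sox2 at 79.5 against 97.3 CPM and Tbx5 at 6.85 CPM against 0 UMIs, at least 27.6-fold higher over the group floor of 3 counts.

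Against mesenchyme, the optic vesicle-like class had more Fgf15 and Hes5 RNA, and less Col3a1 RNA. The 2153 mesenchyme cells joined the crest mesenchyme-like and head mesoderm-like classes, and 21 readout genes were higher, 27 lower and 265 neither, in 5 libraries. Fgf15 was 58.1-fold higher in the vesicle (45.1 to 76.1). Hes5 (ENSMUSG00000048001, chromosome 4, 154960923 to 154962371) was 29.1-fold higher (21.9 to 39.7). Col3a1 (ENSMUSG00000026043, chromosome 1, 45311538 to 45349706) was at 213 CPM in mesenchyme and 2.46 CPM in the vesicle, 86.9-fold lower (75.4 to 101), and its ratio was 0.0252 with nucleus-depleted and mixed clusters counted in.

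All 4 Notch genes past the rule were higher, with the feedback gene Nrarp at 18.1-fold (14.6 to 22.7), Hes1 at 2.87-fold (2.78 to 2.95) and Dtx4 at 3.50-fold beside Hes5. The WNT list gave 4 higher and 4 lower. Wnt7b (ENSMUSG00000022382, chromosome 15, 85535437 to 85582473) was 31.2-fold higher (23.3 to 42.7), Sfrp2 5.0-fold (4.79 to 5.23), Dkk1 5.0-fold (4.41 to 5.68) and Sfrp1 2.90-fold, while Rspo1, a WNT enhancer, was 32.4-fold lower (26.3 to 40.5) and Fzd7, Wls and Nkd1 were lower. The ratio of Rspo1 was 0.102 with doublets kept, 0.050 with nucleus-depleted and mixed clusters counted in and 0.0474 without library 5, and Dkk1 was 2.80-fold higher without library 5 and 9.45-fold without library 3. In the BMP and TGF-beta list Fst (4.83-fold, 4.45 to 5.24, and 7.32-fold without library 3) and Bmp7 (3.18-fold) were higher, and Msx1 (11.4-fold, 10.4 to 12.6) and Bambi were lower. The retinoic acid list gave 0 higher and 3 lower. Its lower members were the receptors Rarg (35.3-fold, 29.4 to 42.8) and Rarb (12.6-fold, 11.2 to 14.4) and the binding protein gene Crabp1, at 126 against 1866 CPM (14.8-fold, 14.5 to 15.1). Aldh1a3 had a ratio of 36.4 (31.7 to 42.1) toward the vesicle but was higher in only 4 of 5 libraries, so it missed the rule.

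Of 24 adhesion and basement membrane genes, 3 were higher and 8 lower. Col18a1 (4.0-fold), Itga6 (3.47-fold) and Cdh2, the neural cadherin gene, were higher, and Nid1 (22.5-fold, 18.3 to 27.9), Col1a2 (19.5-fold, 17.7 to 21.4), Nid2 (7.71-fold), Col4a1 (6.08-fold), Col4a2 (4.91-fold), Vcan (3.18-fold) and Cdh11 were lower. Guidance genes gave 3 higher, among them Unc5b, a netrin receptor gene (9.36-fold, 8.33 to 10.5), Ephb2 and Efna5 (2.05-fold), and 3 lower, Nrp2 (5.11-fold), Efna2 (3.22-fold) and Efnb1. In glycolysis Slc2a3 (6.83-fold, 6.16 to 7.59) and Slc2a1 (3.81-fold, 3.67 to 3.97) were higher and 0 were lower. Imprinted genes gave Plagl1 higher (11.2-fold, 9.85 to 12.8) and H19, Peg3, Igf2 and Peg10 lower. In the FGF list Fgf15 was higher and Dusp6 lower (5.70-fold, 5.20 to 6.24), with a ratio of 0.312 for Dusp6 when the ventral cluster was counted as optic vesicle. Hes6 was the 1 higher of 12 neurogenesis genes, and Gas1 (2.01-fold, 1.94 to 2.09) and Jun were the only Hedgehog and stress genes past the rule, both lower. The S phase, G2 and M phase, heterochronic and sex-linked lists had 0 genes past it.

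Against other forebrain-like cells, which share a neuroepithelial origin with the vesicle, fewer readout genes differed. Unc5b (ENSMUSG00000020099, chromosome 10, 60762593 to 60831581) was 13.9-fold higher in the optic vesicle-like class (11.6 to 16.8), at 47.4 against 3.41 CPM. Fgf15 was 6.33-fold higher (5.67 to 7.09). Wnt8b (ENSMUSG00000036961, chromosome 19, 44493472 to 44514273), a ligand gene of the dorsal forebrain, was 11.6-fold lower (10.4 to 13.1), at 4.35 against 50.6 CPM. In all, 10 genes were higher, 6 lower and 297 neither, from 2172 vesicle cells of 5 libraries against 1181 forebrain cells of 4 libraries.

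The 3 WNT genes past the rule were all lower, with Rspo3 at 5.17-fold (4.65 to 5.75) and Wls, needed for WNT secretion, at 2.81-fold (2.66 to 2.96) beside Wnt8b. Bmp7 (2.19-fold) and the BMP target Id1 (2.08-fold, 1.97 to 2.20) were higher. The guidance list gave Unc5b and Efna5 higher (2.44-fold, 2.29 to 2.61) and the ephrin receptor gene Epha7 lower (3.93-fold, 3.64 to 4.25). Single genes passed in several lists. Cdh11 was 2.74-fold higher (2.47 to 3.04) and Gas1 2.03-fold higher. Lfng was 2.10-fold lower and Slc2a3 2.03-fold lower. Igf2 (7.83-fold, 6.67 to 9.26) and Plagl1 (2.35-fold) were the 2 imprinted genes past the rule. The S phase, G2 and M phase, heterochronic, neurogenesis, sex-linked and stress lists had 0. Shh was at 2.97 against 19.9 CPM, a ratio of 6.70 (5.78 to 7.80) toward the forebrain that fell just short of the 20 CPM minimum. The ventral cluster led by Nkx2-1 and Shh was in neither class, so both levels leave out its Shh RNA. Six6 (21.4-fold), Pax2 (18-fold), Vax2 (20.7-fold) and Mitf (25.3-fold) separated the classes by construction, while Rax (2.41-fold), Lhx2 (2.30-fold), Pax6 (1.40-fold) and Otx2 (1.16 toward the forebrain) had smaller ratios.

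Library 5 had no other forebrain-like cells, so its vesicle cells entered only 1 side. With only the 4 libraries holding both classes, 6 genes were higher and 6 lower, of which 6 and 4 were among those over all libraries. There Igf2 (2.05-fold), Plagl1 (1.91-fold), Bmp7 (1.82-fold) and Gas1 (1.60-fold) no longer met the rule, nor did Lfng and Slc2a3 on the lower side. Unc5b was then 9.82-fold, Fgf15 5.0-fold, Efna5 2.31-fold, Cdh11 2.10-fold and Id1 2.10-fold higher. Vim, with a ratio of 1.72 toward the forebrain over all libraries, was 3.00-fold lower in the vesicle over these 4.

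The classes on either side of this comparison moved with the clustering. With doublets kept, 2414 cells were optic vesicle-like and 876 other forebrain-like, and the ratios of Wnt8b (0.682, 0.623 to 0.748), Wls (0.554) and Slc2a3 (0.855) fell short of the rule, while Rspo3 was at 0.447, Id1 at 3.28 and Gas1 at 3.63. Unc5b was 8.22-fold higher at Leiden resolution 2, the ratio of Wnt8b was 0.0528 with readout lists allowed in the clustering, and Plagl1 (1.21-fold) fell short of the rule with the ventral cluster counted as other forebrain. Libraries weighted equally gave ratios of 2.31 for Igf2, 0.145 for Wnt8b and 0.765 for Slc2a3, and without library 1 Igf2 was 12.4-fold, Id1 3.76-fold and Gas1 3.46-fold higher. Among the markers, Six6 was 7.11-fold higher at Leiden resolution 2 and 2.36-fold with the ventral cluster counted as other forebrain, and over the 4 libraries Pax2 was 11.5-fold, Vax2 11.4-fold and Mitf 14.1-fold higher, while Vax2 was 36.2-fold higher without library 4.

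**Figure D2:**
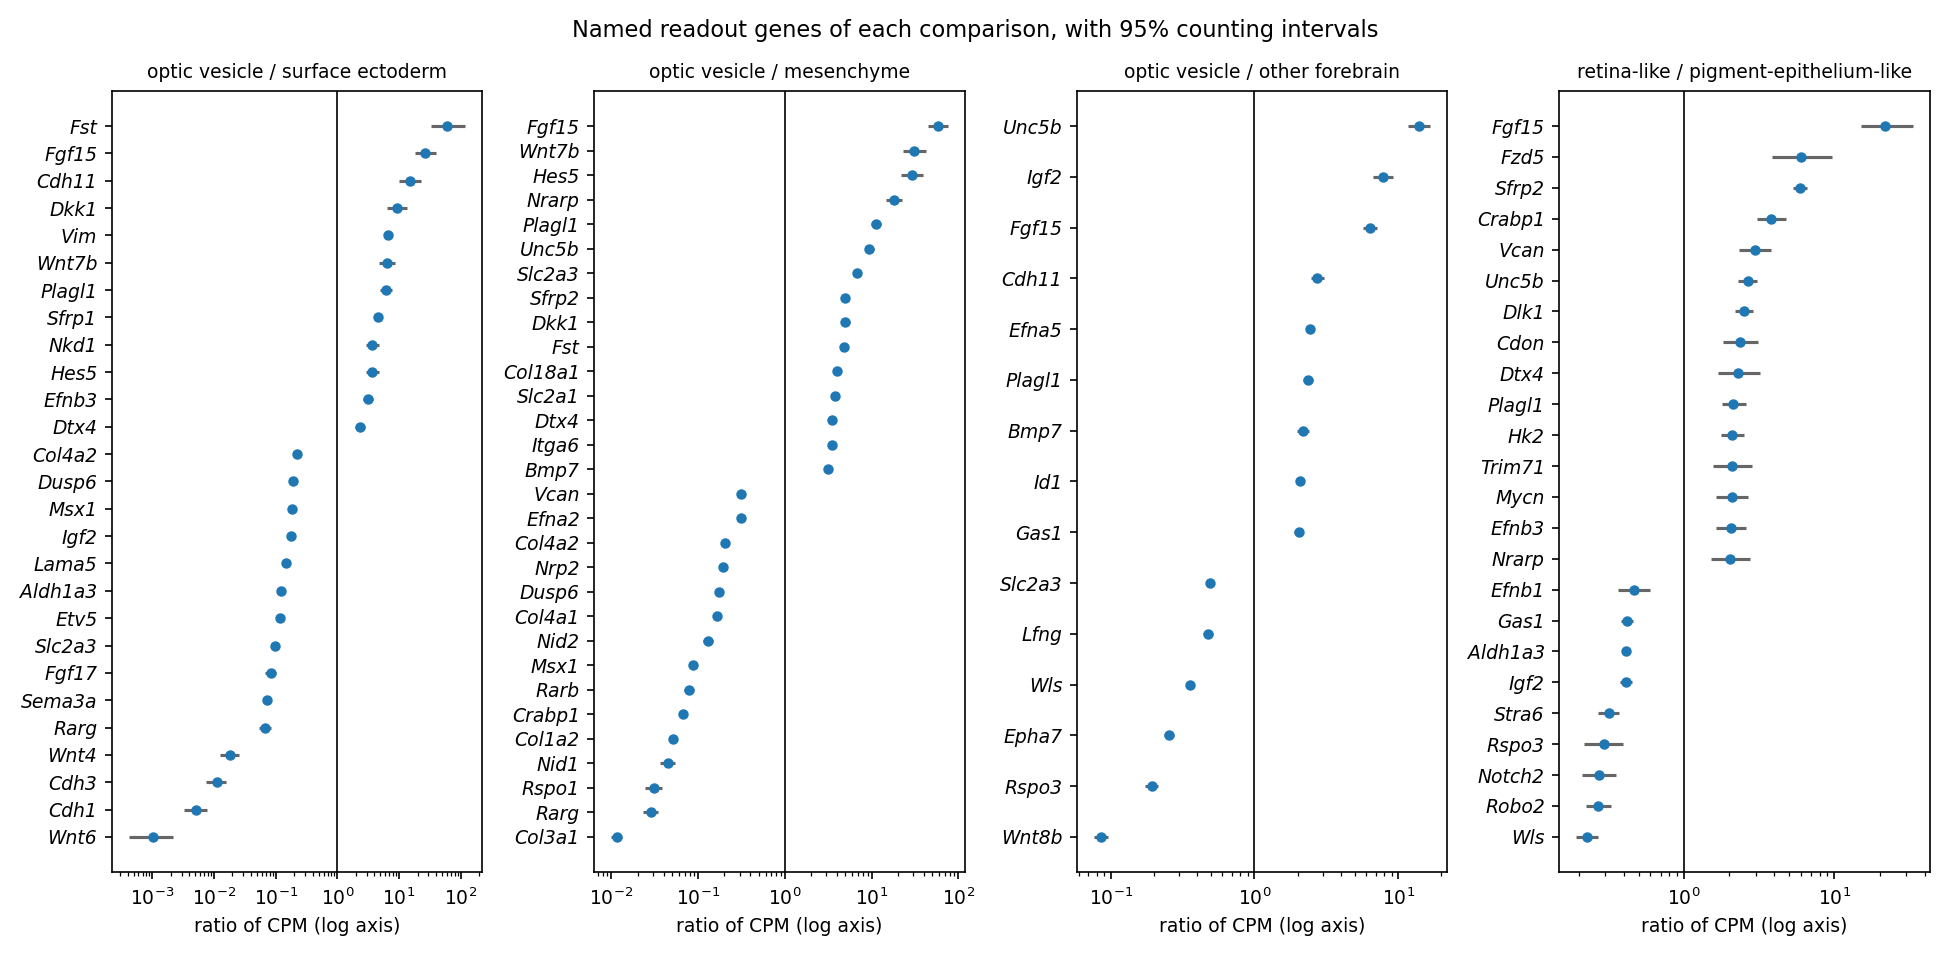
CPM ratio on a log axis, with 95% counting intervals as bars, of readout genes named in each of the 4 comparisons. Ratios above 1 are higher in the optic vesicle-like class (or the retina-like cells), and Wnt6 against surface ectoderm, 962-fold lower, lies farthest from 1.

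Within the optic vesicle-like class, presumptive retina and pigment epithelium could be set side by side in library 5 only. Retina-like cells had more Fgf15 (138 against 6.29 CPM, 21.9-fold, 15 to 33.3), and more Mycn (2.08-fold, 1.64 to 2.65) and Trim71 (2.09-fold). Pigment-epithelium-like cells had more Wls (ENSMUSG00000028173, chromosome 3, 159839672 to 159938664). Wls was at 20.5 against 90.1 CPM, 4.40-fold lower in retina-like cells (3.73 to 5.20). Between 300 and 150 cells, 15 genes were higher in retina-like cells, 9 lower and 289 neither. No stalk-like sub-cluster was named, so that region was not compared.

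In the WNT list Fzd5 (5.98-fold, 3.88 to 9.66) and Sfrp2 (5.92-fold, 5.29 to 6.63) were higher and Wls and Rspo3 (3.40-fold, 2.54 to 4.58) lower. In the retinoic acid list Crabp1 was higher (3.79-fold, 3.06 to 4.75), and the retinol transporter gene Stra6 (3.17-fold, 2.71 to 3.70) and Aldh1a3 (2.41-fold, 2.29 to 2.53) were lower. The Notch list gave Dtx4 (2.31-fold) and Nrarp (2.02-fold) higher and the receptor Notch2 lower (3.65-fold, 2.82 to 4.73). Guidance genes gave Unc5b (2.66-fold, 2.30 to 3.08) and Efnb3 (2.06-fold) higher and Robo2 (3.70-fold, 3.05 to 4.50) and Efnb1 (2.14-fold) lower. Cdon was higher (2.37-fold) and Gas1 lower (2.40-fold, 2.19 to 2.63) among Hedgehog genes, and Dlk1 (2.51-fold) and Plagl1 (2.14-fold) higher and Igf2 lower (2.42-fold, 2.22 to 2.65) among imprinted genes. Vcan (2.96-fold, 2.33 to 3.80) and the hexokinase gene Hk2 (2.09-fold) were the only adhesion and glycolysis genes past the rule, both higher. The BMP and TGF-beta, S phase, G2 and M phase, neurogenesis, sex-linked and stress lists had 0, with Bmp4 at 1.15-fold (0.970 to 1.36) and Bmp7 at 1.57 toward the pigment-epithelium-like cells. The level of Mitf (48.5 against 144 CPM) reflects how the regions were named. All of these cells but 4 came from 1 embryo, with a median depth of 32233 UMIs in retina-like and 24219 UMIs in pigment-epithelium-like cells.

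Across the 4 comparisons the best-covered members of several lists stayed below the rule. Gapdh and Ldha of glycolysis, Hmgb2 and Cks2 of G2 and M phase, Rrm2 of S phase, Id2 and Id3 of the BMP list, Fgfr1 and Smo, Crabp2, Hmga2 and Igf2bp1, Sox11 and Sox4, Mest and Meg3, and Btg1 each differed by less than 2-fold in every comparison. The largest of these ratios were 1.98 for Crabp2 against mesenchyme and 1.96 for Id2 against other forebrain.

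Within the optic vesicle-like class, Xist, Aldh1a1, Eif2s3y, Fgf17, Nkx2-1 and Aldh1a3 had the largest ratios between libraries among readout and marker genes. Of 455 readout and marker genes, 83 differed at least 4-fold between the highest and the lowest library. The highest value lay in library 5 for 38 of them, in library 1 for 26, in library 2 for 13, in library 3 for 4 and in library 4 for 2. Library 5 also had the highest median mitochondrial share, 2.58% of UMIs per barcode against 1.35 to 1.76% in the others, and its vesicle sub-cluster 13 had a median of 14419 UMIs, 0.698 of the median of its library. Without the clusters of low UMI content in library 5, 82 genes differed. The class summed 6039689, 11582712, 25287779, 12554462 and 23926317 UMIs in libraries 1 to 5. Most of its cells lay in sub-cluster 2 in library 1 (200 of 202), in sub-clusters 4 and 2 in library 2 (268 and 82 of 357), in 5 and 6 in library 3 (278 and 240 of 522), in 9 in library 4 (237 of 279), and in 10, 11, 12 and 13 in library 5 (147, 299, 220 and 142 of 812). Libraries thus contributed different sub-clusters, as well as different embryos.

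Genes of retinoic acid synthesis differed between libraries. Aldh1a1 (ENSMUSG00000053279, chromosome 19, 20492715 to 20643465) was at 0, 0.777, 3.24, 33.8 and 175 CPM in libraries 1 to 5. Aldh1a3 was at 1.49, 14.4, 30.1, 109 and 308 CPM, and Aldh1a2 at 16.7, 3.97, 3.88, 0.319 and 0.251 CPM. With Stra6 among them, 5 of 15 retinoic acid genes differed 4-fold, 4 of them highest in library 5. The pigment genes Pmel (1.32, 0.259, 0.672, 6.53 and 44.4 CPM) and Dct (0, 0.259, 0.316, 7.41 and 42.2 CPM) were highest in library 5. Vax2, of the ventral retina, was at 1.32, 13, 18.9, 64.5 and 96.8 CPM, and Hmx1 at 0, 0.863, 2.02, 32.3 and 48.4 CPM.

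Other genes were highest elsewhere. Fgf17 was at 26.0 CPM in library 1 and at most 0.319 CPM in the others, and with Fgf8, Fgf3 and Etv4 among them 9 of 21 FGF genes differed 4-fold, 7 of them highest in library 1. Fgf8 was at 56.8, 1.73, 2.13, 3.27 and 6.77 CPM. The forebrain regulator Emx2 (ENSMUSG00000043969, chromosome 19, 59458372 to 59465357) was at 46.7, 18.9, 6.68, 3.58 and 0.460 CPM, Stmn2, a neuronal gene, at 61.6, 15.5, 15.1, 2.55 and 0.961 CPM, and Trh at 31.1, 1.12, 0.158, 0.159 and 0.627 CPM. Nkx2-1 was at 1.32, 26.0, 17.9, 4.78 and 0 CPM, Nkx2-9 at 2.65, 11.6, 18, 5.97 and 0 CPM, and Shh at 1.32, 5.87, 5.97, 0.717 and 0 CPM, beside shares of the ventral cluster led by Nkx2-1 and Shh of 0.235%, 7.80%, 6.90%, 4.78% and 0.115% of the same libraries. Notch genes gave Dll1, Hes5 and Lfng, all highest in library 1, with Hes5 at 59.4, 50.5, 26.8, 12.7 and 2.38 CPM, whereas the whole list of 18 summed to 355, 454, 376, 414 and 529 CPM, lowest in library 1. Of the sex-linked genes, Xist was at 751 and 886 CPM in libraries 1 and 5 and at most 0.086 CPM in libraries 2, 3 and 4. Eif2s3y (34.7, 17.6 and 22.9 CPM) and Ddx3y (18.6, 11 and 10.7 CPM) were found in libraries 2, 3 and 4. So were Kdm5d (13.8, 5.30 and 6.13 CPM) and Uty (9.67, 5.22 and 6.53 CPM). All of these had 0 UMIs in libraries 1 and 5. Xist, Ddx3y and Eif2s3y had the same pattern in crest mesenchyme-like and endothelium-like cells. By these genes, libraries 1 and 5 read as female and libraries 2, 3 and 4 as male.

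Members of other lists differed as well. These were 6 of 35 WNT genes (Wnt7b, Wnt8b, Frzb, Dkk1, Dkk3 and Wif1), 4 of 27 BMP and TGF-beta genes (among them Bmp4 at 4.30, 11.5, 11.9, 21.1 and 33.4 CPM), 9 of 28 guidance genes, 2 of 12 Hedgehog genes (Shh and Gli1), 2 of 12 neurogenesis genes (Neurog2 among them) and 3 of 14 imprinted genes (H19, Igf2 and Plagl1, all highest in library 5). In the adhesion list Nid2 and Vim differed, with Vim (ENSMUSG00000026728, chromosome 2, 13573927 to 13582826) at 18, 24.8, 49.4, 156 and 225 CPM. In glycolysis Slc2a3 (127, 74.8, 50.4, 27.5 and 16.3 CPM), Pgk1 and Slc16a3 differed. The S phase, G2 and M phase, heterochronic and stress lists had 0 genes at 4-fold. Of the eye-field regulators, Rax lay between 135 and 176 CPM (median 148), Lhx2 between 202 and 285 CPM (median 256) and Pax6 between 174 and 280 CPM (median 210), Otx2 between 81.3 and 146 CPM, and Sox2 between 69.2 and 118 CPM. Rax (ENSMUSG00000024518) lies at 65928277 to 65939787 on chromosome 18, Lhx2 (ENSMUSG00000000247) at 38339281 to 38369733 on chromosome 2 and Pax6 (ENSMUSG00000027168) at 105668900 to 105697364 on the same chromosome. Six3 ran from 115 to 192 CPM, Six6 from 134 to 326 CPM, Pax2 from 25.0 to 96.3 CPM, Mitf from 5.63 to 64.5 CPM, Tbx5 from 1.16 to 14.1 CPM, Bmp7 from 22.3 to 42.4 CPM and Fgf15 from 33.3 to 87.2 CPM. Vax1 stayed at or below 0.752 CPM and Foxe3, a lens gene, at or below 0.042 CPM.

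Marker lists of other cell types were also measured in this class, which does not tell RNA of other cells from RNA of its own. The 9 erythroid markers summed to 251, 649, 142, 183 and 203 CPM in libraries 1 to 5. Of these, 5 globin genes differed 4-fold with their highest value in library 2, among them Hba-a1 and Hba-a2, near-identical copies that can share reads. Of the telencephalon list 4 of 6 genes differed (Emx2 and Sp8 among them), of the diencephalon and hypothalamus list 2 of 7 (Nkx2-1 and Lhx5), of surface ectoderm 2 of 9 (Krt8 and Cldn6), of neuron 2 of 8 (Elavl3 and Stmn2), and of endothelium (Kdr), myeloid (Fcer1g) and endoderm (Trh) 1 gene each. The midbrain and hindbrain, lens placode, other placode, crest mesenchyme, migratory crest, head mesoderm, megakaryocyte and extraembryonic endoderm lists had 0. Of the optic vesicle list 5 of 10 differed, of neural retina 3 of 5, of retinal pigment epithelium 4 of 7, of optic stalk 2 of 4 and of dorsal optic vesicle 3 of 4 (Tbx5, Tbx2 and Tbx3).

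**Figure D3:**
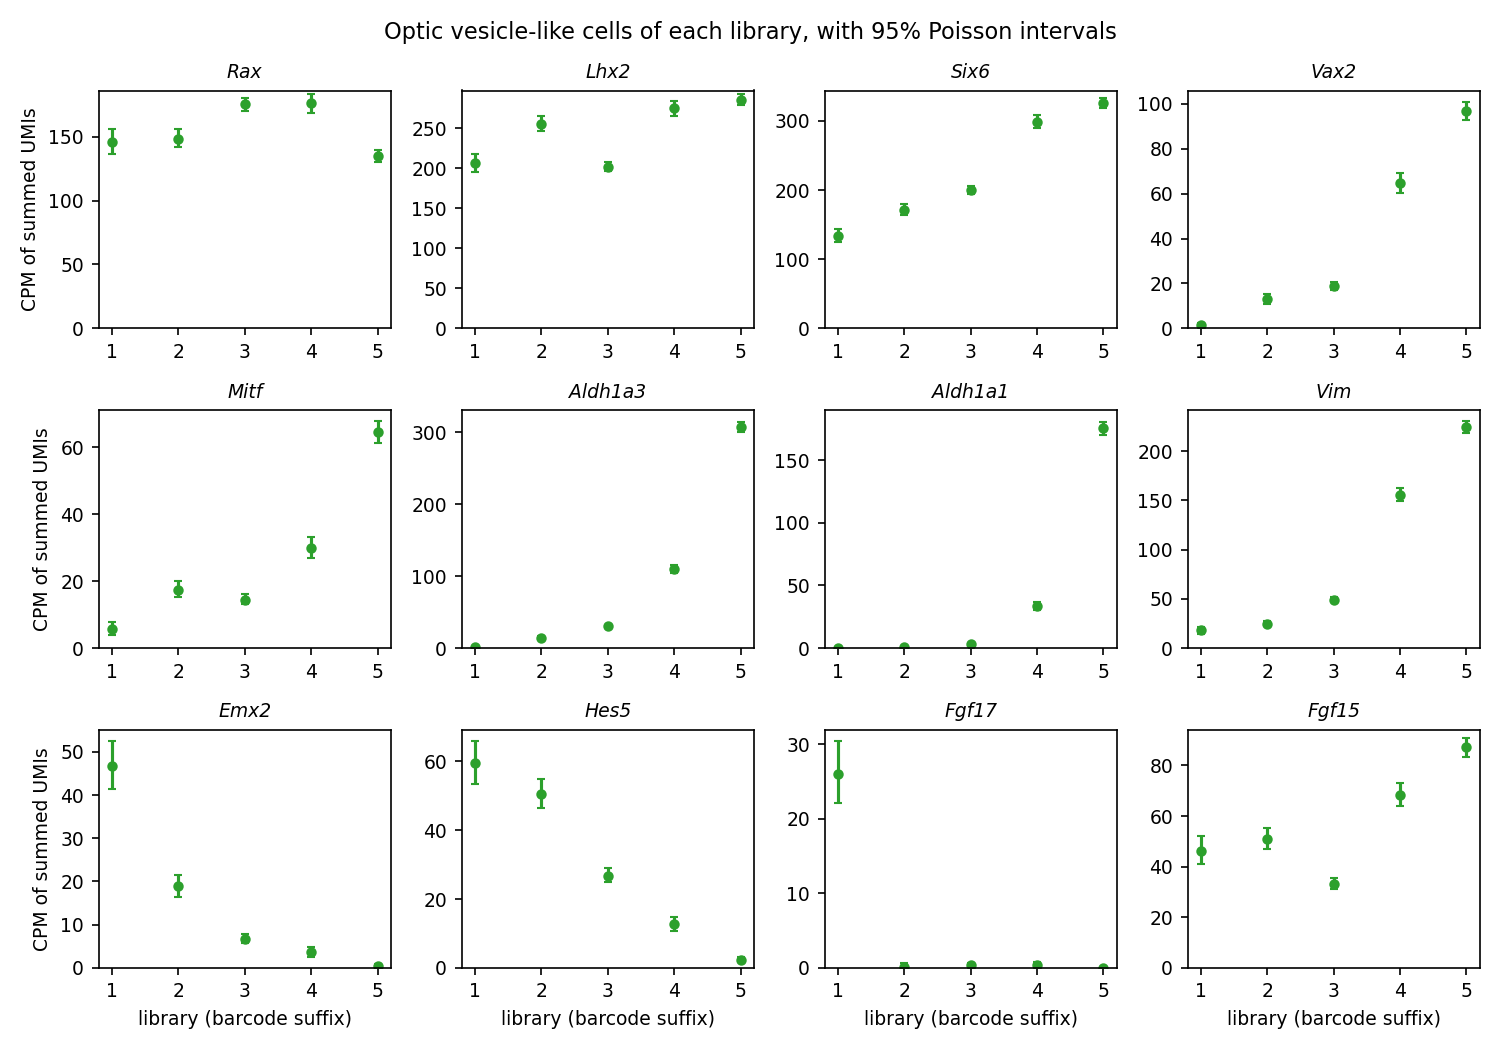
CPM (vertical axes, from 0) of 12 genes in optic vesicle-like cells of each library, with 95% Poisson intervals that cover counting error only. Aldh1a1 runs from 0 in library 1 to 175 CPM in library 5 while Rax stays between 135 and 176 CPM, and library numbers are not assigned to stages.

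The cell cycle score was computed for 8 named classes and the ventral cluster. After thinning to 5000 UMIs, a positive G2 and M score was found in 93.6% of optic vesicle-like cells (92.5 to 94.6%), 96.7% of other forebrain-like (95.5 to 97.6%), 94.5% of crest mesenchyme-like (93.3 to 95.5%) and 85.1% of surface ectoderm-like cells (81.1 to 88.4%). The ventral cluster was at 86.7%, head mesoderm-like cells at 93.5%, endothelium-like at 85.8%, erythroid-like at 83.8% and migratory crest-like at 77.5%. Without thinning, the same classes were at 97.6%, 99.7%, 99.1%, 89.2%, 92.0%, 97.7%, 89.9%, 94.1% and 77.5% in that order. Most cells of each class scored were thus positive, so the score separates the classes poorly, and it does not by itself show that a cell was cycling. The S phase list summed to 2730 CPM in optic vesicle-like cells (2699 to 2761), 3168 CPM in other forebrain-like, 2464 CPM in crest mesenchyme-like and 2273 CPM in surface ectoderm-like cells. The G2 and M list summed to 5932, 6383, 5508 and 5344 CPM in the same classes. In the optic vesicle-like class, 98.5%, 96.1%, 97.1%, 94.6% and 88.8% of cells scored positive in libraries 1 to 5.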

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

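The tests for empty droplets, for dying cells and for doublets, and the comparison of long intergenic RNAs with coding genes, were chosen after these results were seen. A test of dying cells on the nuclear RNAs Kcnq1ot1, Meg3 and Xist, at most 0.107 of the named cells, was set aside after its values were seen. The reason was that the clusters were picked for little Malat1, itself a nuclear RNA, and the mitochondrial share was used.

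Barcodes with little Malat1 (ENSMUSG00000092341), a nuclear RNA, made up 9.74% of the cells kept and enter the comparisons only under an alternative, and no biological explanation was tested. They formed 4 clusters with 0.112, 0.0377, 0.0522 and 0.0402 of the Malat1 CPM of named cells of the same libraries. Empty droplets are argued against by crest markers in the clusters compared. The CPM of these markers in a cluster with optic vesicle RNA was a median 0.0441 (0.0140 to 0.0986) of that in a cluster with crest RNA from the same 3 libraries. The other clusters were not compared in this way. Dying cells that lost cytoplasmic RNA are argued against by the mitochondrial share in 3 clusters, at 0.656 (0.582 to 0.744), 0.0349 (0.0249 to 0.056) and 0.0704 (0.0318 to 0.207) of that of named cells. In the cluster with the highest Malat1 this share was 2.29 (1.96 to 2.57) of that of named cells, and dying cells stay open. The nuclear RNAs Kcnq1ot1, Meg3 and Xist go the other way there, at 0.103, 0.0951 and 0.107 of named cells. Pieces of cells without a nucleus may remain a candidate explanation, since other long intergenic RNAs had a median ratio of 0.728 (0.601 to 0.922) in the cluster where it was highest, which met the bound set beforehand. Coding genes of matched level fell about as far (0.873, 0.561, 0.467 and 0.569 in the 4 clusters, against 0.728, 0.577, 0.393 and 0.519), so these pieces and other losses of RNA cannot be told apart.

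Cells with optic vesicle and crest markers together made up 3.33% of the cells kept, and no biological explanation was tested. Both marker sets were found in 95.1% of the 222 cells that the larger cluster had in libraries 3 and 4, against 16.1% of optic vesicle-like and 18.3% of crest mesenchyme-like cells of the same libraries. The shares are not matched for depth, with median UMIs of 58540, 39105 and 28800 in turn. Both clusters were set apart for carrying such markers, so the shares describe that choice. The rise of the crest list, 8.35-fold over optic vesicle-like cells in the larger cluster, likewise follows from that choice. Free RNA of all lineages would also raise the endothelium and erythroid lists, for which the clusters were not picked. These lists were at 0.989 (0.898 to 1.09) and 1.13 (1.08 to 1.19) of optic vesicle-like cells there, and at 0.958 and 1.04 in the smaller cluster. On the log scale they rose by at most 0.0580 (0.0356 to 0.0802) as much as the crest list. Free RNA of all lineages is thus argued against, while free RNA of crest alone was not tested. Doublets missed by the caller stay open and are consistent with the depth, since the median UMIs were 0.862 and 0.944 of the summed medians of the 2 classes in the 2 clusters, by a bound set after these depths were seen.

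The unnamed ventral cluster led by Nkx2-1 and Shh held 4.18% of the cells kept.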

How the results depend on the processing

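The alternatives that took the nucleus-depleted and mixed clusters out of the total, or summed only libraries with at least 30 cells of both classes, were chosen after seeing the data. Of the main values under alternatives, 131 stayed within their interval, or within 1.5 times for a count, and 34 moved. Of the single genes and other values, 3172 stayed and 1070 moved. No named gene past the size rule changed direction under an alternative, but some genes short of it did, among them Xist against surface ectoderm (a ratio of 1.54, and 0.865 with libraries weighted equally). The optic vesicle-like share was 29.5% with doublets kept, 25.3% at Leiden resolution 2, 24.2% with readout lists allowed in the clustering, 30.8% without nucleus-depleted and mixed clusters, and 21.4 to 28.9% with each library left out in turn. At a ratio of at least 1.5, 22 genes were higher than in surface ectoderm, 16 lower than in other forebrain, and 25 higher and 25 lower between retina-like and pigment-epithelium-like cells. At a ratio of at least 3, 19 genes were lower than in surface ectoderm, 17 lower than in mesenchyme, 4 higher and 3 lower than in other forebrain, and 4 higher and 5 lower between the regions. With no minimum of UMIs or CPM, the higher and lower counts were 20 and 51 against surface ectoderm, 44 and 56 against mesenchyme, 30 and 23 against other forebrain, and 26 and 15 between the regions. A looser or stricter rule changes such counts by construction. Against other forebrain, 6 genes were higher with libraries weighted equally, 6 with libraries holding at least 30 cells of both classes, and 6 without library 5, and 10 were lower without library 3. With each library left out, higher and lower counts ran from 9 to 15 and 27 to 33 against surface ectoderm, 19 to 26 and 27 to 29 against mesenchyme, and 6 to 14 and 6 to 10 against other forebrain, and stayed at 15 and 9 between the regions, where leaving out library 5 gives no comparison. Across libraries 170 genes differed at least 2-fold, 48 at least 8-fold, and 59 to 81 at least 4-fold with a library left out. The G2 and M share was 97.6% unthinned and 76.5% after thinning to fewer UMIs. Except for the changed rules, the cause was not tested. Lens placode was not compared, since no sub-cluster led by its markers was found, and no stalk-like region was named. A test paired within libraries was not run, since unassigned libraries of different stages were not treated as replicates, and the direction in each library was used in its place.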

Other observations

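The test of a whole-library effect was set before its result was seen, while its repeat without sex-linked and erythroid genes was chosen after, and the genes named in the next 2 paragraphs were chosen after their values were seen.

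Outside the readout and marker lists, 516 genes differed at least 4-fold between libraries in the optic vesicle-like class. Trpm1 (ENSMUSG00000030523), a channel gene of pigment cells and retina, was at 0, 2.76, 4.86, 36.3 and 161 CPM in libraries 1 to 5. Col9a1 (ENSMUSG00000026147), a collagen gene, was at 8.61, 28.7, 29.7, 115 and 198 CPM. Tfec, of the same transcription factor family as Mitf, had 0 UMIs in libraries 1, 2 and 3 and was at 0.478 and 3.43 CPM in libraries 4 and 5. Hesx1 (ENSMUSG00000040726), a homeobox gene of the anterior neural plate, was at 43.2, 4.32, 2.89, 0.797 and 0.167 CPM. Tal2 (ENSMUSG00000028417) was at 27.5, 5.09, 3.48, 0.398 and 0.251 CPM and Eras (ENSMUSG00000031160) at 43.7, 11.4, 10.8, 3.82 and 0.961 CPM. The ventral regulator Nkx2-2 was highest in library 3, at 1.32, 4.92, 7.28, 5.34 and 0.251 CPM. Whether the library numbers follow the order of the stages is not given.

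With at least 50 UMIs in the highest library of each class, 5 genes differed at least 8-fold between libraries in optic vesicle-like, crest mesenchyme-like and endothelium-like cells alike, and genes with fewer UMIs in the smallest class could not enter. These were Xist, Ddx3y, Eif2s3y, Gm5900 and Hist1h2ap. The pseudogene Gm5900 (ENSMUSG00000094685, chromosome 7, 104949915 to 104950289) was at 0.331, 28.2, 0.040, 0.159 and 32.6 CPM in the vesicle and at 0, 33.3, 0, 0.100 and 29.2 CPM in crest mesenchyme. Hist1h2ap was at 141, 113, 1564, 421 and 328 CPM in the vesicle and at 118, 92.2, 1457, 386 and 220 CPM in crest mesenchyme. Both have near-identical copies, so their counts are uncertain.

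Of the 83 readout and marker genes that differed between libraries in the optic vesicle-like class, 43 could be compared in crest mesenchyme-like cells of the same libraries. A whole-library effect on these genes, technical or of the embryo, would move both classes, and the median share of the log2 difference found in crest was 0.733 (0.403 to 0.930), an interval that includes the bound of 0.5. Without 10 sex-linked and erythroid genes the median of the other 33 was 0.546 (0.134 to 0.800), which includes it too. It could therefore not be excluded for the set, and it cannot be told apart from differences in development or in the sub-clusters each library contributed. For 9 genes crest differed in the opposite direction, among them Emx2, with a log2 difference of 6.61 in the vesicle and -4.22 in crest. No biological explanation was tested, since the libraries name no stage.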
